A study of Mus musculus musculus x Mus musculus castaneus with 7 samples.

How the data were processed

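RNA from female mouse cells of a musculus × castaneus cross was sequenced in 7 libraries, 1 for each of 7 groups. The groups were a Day 2 reprogramming intermediate, SSEA1-positive intermediates of Days 8, 10, 13 and 15, induced pluripotent stem cells (iPSCs) and embryonic stem cells (ESCs). Per the labels' protocols, embryonic fibroblasts received doxycycline-inducible lentiviral Pou5f1, Sox2, Klf4 and Myc with the M2rtTA activator. Also per the labels' protocols, fibroblasts were sorted by which X chromosome carried the active X-GFP reporter, and reprogramming was induced with 2 µg/ml doxycycline in serum medium with LIF and ascorbic acid. The iPSCs came from picked colonies kept without doxycycline and ascorbic acid, per the labels' protocols. SSEA1, a surface glycan of mouse pluripotent cells, was the sorting antigen of the later intermediates, and the iPSCs and ESCs were sorted for SSEA1 and GFP, per the labels. Per the labels' protocols, RNA of the stored samples was extracted together, cDNA was made from 500 pg of RNA and the libraries were made with the Nextera XT kit. That kit does not mark the strand, so reads of a gene and of an overlapping antisense gene could not be told apart.

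Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.5.3a and counted with featureCounts on the mm10 (GRCm38.p5) genome. The counts were not split by allele. The values deposited by the authors were on the log2 scale: log2 of the reads per gene divided by a size factor per library, plus 1. The method of the size factors is not given in the sources used here. Undoing the logarithm gave whole multiples of the value of 1 read for 100% of the values of each library, within a tolerance of 0.01 reads, so read numbers were recovered. The recovered factors equalled median-of-ratios factors over the 11395 genes with reads in all 7 libraries to within 1e-13 percent.

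The table held 24393 genes. Of these symbols, 23485 were matched to chromosome positions and gene types of GENCODE M21, and 908 unmatched symbols stayed in the gene counts and out of results by chromosome. Reads of families of near-identical genes (the Xlr, Rhox, Magea, Usp17l, Zscan4 and Tdpoz families, and Tuba3a with Tuba3b) can be shared or lost in alignment, so their values are uncertain.

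With 1 library per group no spread between replicates could be had. No test between groups was run on the values or on the recovered reads, and no p-value is given. For each of 7 comparisons the log2 values of 2 libraries were subtracted. Genes were compared where the higher library was at or above 6 on the log2 scale (64 normalized counts), and were counted as higher or lower at a difference of at least 2 (4-fold). Members of gene lists were counted at a difference of at least 1 (2-fold). A list member counted as measured at a mean of at least 4 or a highest value of at least 6. Each list's median difference was ranked among 10000 random lists of the same size, drawn with seed 1 from genes in the same of 20 bins of mean value. The percentile describes the 2 libraries and is no test of the groups.

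Folds are ratios of normalized counts. Against a library with 0 reads, a fold was computed against a floor of 3 reads in that library and is written as at least that large. Intervals given after other folds are 95% Clopper-Pearson intervals of the read counts, and not every fold is printed with its interval. The floor of 3 reads was worth 2.74, 2.45, 2.33, 2.93, 1.74, 7.03 and 3.24 normalized counts in the Day 2, Day 8, Day 10, Day 13, Day 15, iPSC and ESC libraries. The reads carried no molecular identifiers, so counting intervals and floors cover counting error only.

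Genes on chromosome X were compared with autosomal genes, both with a mean at or above 6 over the 7 libraries, as the difference of the medians, with an order-statistic 95% interval of the X-linked median. That difference was ranked among 10000 random autosomal lists matched on mean value. A fallback list of X-linked genes, fixed in advance for the case that positions could not be had, was scored as a gene list. For the course over time, each gene counted in iPSC minus Day 2 was placed by whether an intermediate had passed the midpoint of its log2 change, with a 95% Wilson interval of the share of genes. Transient genes had their lowest value over the 4 sorted intermediates at least 1 above the highest of Day 2, iPSC and ESC, or the mirror image.

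The comparisons, thresholds and 29 gene lists were fixed before the data were examined. The lists were pluripotency, formative and primed pluripotency, two-cell-like, germline, fibroblast and mesenchymal, epithelial, X inactivation regulators, X inactivation escapees, X-linked germline families, DNA methylation enzymes, proliferation, p53 and senescence, glycolysis, oxidative phosphorylation, mitochondrial genome, ribosomal proteins, interferon response, inflammation, immediate early, MAPK targets, epidermal, trophoblast, primitive endoderm, neural, muscle, blood and macrophage, endothelial, Hox and imprinted genes. Named genes were the 8 largest and 8 smallest differences in iPSC minus Day 2, Day 8 minus Day 2, iPSC minus Day 15 and ESC minus iPSC, and the 4 largest and 4 smallest in the others. Provisional symbols, ribosomal protein pseudogenes and mitochondrial genes were left out of that ranking. Added to these were up to 4 members per list with the largest absolute difference in the comparison described, the 10 transient genes furthest above and 5 furthest below, the 5 X-linked genes with the largest and the 5 with the smallest difference in iPSC minus Day 2 and ESC minus iPSC, and 22 genes of X inactivation, reprogramming and pluripotency. Text on a comparison prints some or all of the genes the rule names.

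Alternatives were a filter at 8, a filter at 4, no filter, centring each library on its median, a pseudocount of 16, X-linked genes that differed by less than 2 between Day 2, iPSC and ESC, 25% and 75% of the way in place of the midpoint, and a margin of 2 for transient genes. After the data had been seen, alternatives were added that swapped or left out libraries, kept only genes with reads in the compared libraries, left out chromosome 1, and removed an iPSC share from the Day 15 values. The code was run on simulated data with counting noise only, which hold no loss of transcripts from low-input cDNA. The changed genes were well expressed, so the 4-fold cut fixed in advance which changes would be counted. Of 100 genes changed 8-fold in a simulated pair 100% were counted, of 100 changed 2-fold 0% were counted, and 94.5% of 200 lists without effect lay in the central 95% of random lists. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.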

Results

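The series followed female mouse embryonic fibroblasts through reprogramming to iPSCs, with the erasure of random X-chromosome inactivation as its subject. Gene expression was measured by RNA sequencing in 7 libraries, 1 per group. The groups were an intermediate labelled Day 2, intermediates sorted for SSEA1 on Days 8, 10, 13 and 15, iPSCs sorted for SSEA1 and GFP, and ESCs sorted for both as well. There were no replicates, so no replicate check was possible and every difference is between 2 libraries. Reads assigned to genes numbered 49549757 at Day 2, 41520563 at Day 8, 42899719 at Day 10, 34687308 at Day 13, 57021069 at Day 15, 15370903 in iPSCs and 37713139 in ESCs. Genes with at least 1 read numbered 16336 at Day 2, 14400 at Day 8, 19524 at Day 10, 20923 at Day 13, 21326 at Day 15, 18196 in iPSCs and 18330 in ESCs. Mitochondrial transcripts took 20.9% of reads in ESCs, against 1.72% at Day 2, 5.33% at Day 8, 2.55% at Day 10, 2.22% at Day 13, 5.61% at Day 15 and 2.79% in iPSCs. Nuclear ribosomal RNA took between 4.32% (ESCs) and 14.9% (Day 2). The mitochondrial ribosomal RNA mt-Rnr2, part of the mitochondrial share, took 6.39% in ESCs.

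Across 11351 genes, which are not independent replicates, Pearson's r was highest between Days 10 and 13 (0.906), followed by Days 13 and 15 (0.892) and iPSCs and ESCs (0.864). Day 8 stood furthest from the iPSCs (0.43), and r between Days 2 and 8 was 0.462. The library labelled Day 2 held 0 reads of Pou5f1 and 0 of Sox2, against 309 of Klf4 and 9773 of Myc, the 4 genes carried by the reprogramming vector. These values do not show induction of the vector in that library, so a comparison with it is not known to start from induced cells. Its label also names no SSEA1 sort, unlike the labels of the other 6 libraries. Time and the selection of SSEA1-positive cells therefore cannot be told apart in any comparison with Day 2. Genes with at least 256 normalized counts in each of the other 6 libraries had no read in 116 of 6971 cases (1.66%) at Day 2 and in 153 of 7052 cases (2.17%) at Day 8. The other 5 libraries lacked 0 to 2 such genes, so a value of 0 in the Day 2 or Day 8 library is a weaker measurement of absence than in the others.

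The comparison of iPSCs with Day 2 sets the end of the course against the earliest library. Pluripotency genes were among those furthest above the Day 2 library. Dppa5a, a marker of undifferentiated stem cells, was at least 75535-fold higher in iPSCs, and Zfp42 (Rex1) at least 11023-fold. Pou5f1, the core pluripotency factor encoding Oct4, was at least 8297-fold higher, Utf1 at least 10252-fold, the chromatin factor Epop at least 7918-fold, the Nodal co-receptor Tdgf1 at least 7496-fold, and the naive pluripotency factor Tfcp2l1 at least 6600-fold. The X-linked gene Bex1 was at least 14303-fold higher. Of the genes furthest below, Lox, which cross-links collagen, was at least 13095-fold lower, the activin subunit gene Inhba at least 5212-fold, Ccdc80 at least 4440-fold, and Lrrc32 at least 4140-fold. The receptor kinase Axl (at least 4042-fold lower), the smooth muscle actin Actg2 (at least 3557-fold) and the chemokine Ppbp (at least 2852-fold) followed, with tenascin C (Tnc) at 24752 normalized counts at Day 2 and 0 in iPSCs.

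All 45 measured pluripotency genes were at least 2-fold higher in iPSCs than in the Day 2 library, with a median difference of 12.01 on the log2 scale, or 10.10 with zeros set to 3 reads. Nanog had 3 reads at Day 2 and 13328 in iPSCs, a ratio of 11385 (95% interval 3895 to 55213). Sox2 was at least 1162-fold higher, Esrrb at least 3108-fold, Dppa4 at least 1440-fold and Prdm14, a repressor of DNA methylation in the germ line, at least 641-fold. All 48 fibroblast and mesenchymal genes were lower, with a median of -8.21, or -6.77 with zeros at 3 reads, and among them the limb mesenchyme factor Prrx1 was at least 1712-fold lower, collagen VI (Col6a3) at least 1209-fold and the PDGF receptor Pdgfrb at least 545-fold. Thy1, the surface antigen of fibroblasts, was 8.86-fold lower (6.9 to 11.6). All 23 measured Hox genes, which mark body position, were lower, with a median of -7.23 (-4.23 with zeros at 3 reads); Hoxc9 was at least 71.5-fold lower and Hoxc10 at least 63.1-fold.

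Among 29 germline genes 27 were higher in iPSCs than at Day 2 and 0 lower, with a median of 9.90 (8.57 with zeros at 3 reads). The germ-cell RNA-binding gene Dazl was at least 2286-fold higher, and Hormad1, which acts on meiotic chromosome axes, at least 1793-fold. Of 26 X-linked germline genes 25 were higher, with Xlr3a at least 2410-fold and Rhox6 at least 718-fold higher. Of 24 epithelial genes 20 were higher and 1 lower (median 6.16, or 5.13 with zeros at 3 reads): E-cadherin (Cdh1) was at least 1764-fold higher and the adhesion molecule Epcam at least 1355-fold. Formative and primed pluripotency genes were higher in 14 and lower in 1 of 17 (median 5.19, or 3.77 with zeros at 3 reads), led by Otx2 at least 771-fold. Each of these lists lay at percentile 100 of the random lists, and the fibroblast and Hox lists at percentile 0.

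Immediate early genes, which respond to growth signals, were lower in iPSCs in 14 and higher in 1 of 16 (median -3.64, percentile 0), with Fosl2 at least 412-fold lower and Fosl1 85-fold lower (53.7 to 144). Inflammation genes were lower in 10 and higher in 4 of 18 (median -3.44, or -2.83 with zeros at 3 reads; percentile 0). The adhesion molecule Vcam1 was at least 353-fold lower and the chemokine Cxcl5 went from 3710 reads at Day 2 to 12 in iPSCs, while Cxcl10 was at least 37.6-fold higher. Among 24 p53 and senescence genes 11 were lower and 4 higher (median -0.81, percentile 0.45). The cell-cycle inhibitors Cdkn2b and Cdkn2a were 19.9-fold (16.1 to 24.8) and 14.7-fold (8.85 to 26.5) lower, and the death receptor Fas at least 40.2-fold. Myc was 5.46-fold lower (5.06 to 5.91) and Klf4 5.78-fold higher (5.05 to 6.63). Proliferation genes were higher in 14 and lower in 1 of 29 (median 0.82, percentile 99.7), with the replication licensing genes Mcm3 6.78-fold (6.56 to 7.02) and Mcm6 5.3-fold (5.16 to 5.44) higher.

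DNA methylation enzymes were higher in 7 and lower in 1 of 14 (median 1.36, percentile 99.9). Their cofactor Dnmt3l was at least 3589-fold higher, the de novo methyltransferase Dnmt3b 50.9-fold (42.3 to 61.9) and the 5-methylcytosine oxidase Tet1 46.9-fold (41.8 to 52.8). Glycolysis genes were higher in 5 and lower in 2 of 19 (median 0.65, percentile 94.8), among them the glucose transporter Slc2a3 at 136-fold (118 to 157). Of 12 MAPK targets 5 were higher and 2 lower (median 0.63, percentile 93.3), and Klhl13 was 24.7-fold higher (23 to 26.5). Oxidative phosphorylation genes were within 2-fold in 39 of 40 (median -0.07, percentile 6.09) and ribosomal protein genes in 38 of 39 (median -0.26, percentile 0.52). Interferon response genes were higher in 10 and lower in 6 of 23 (median 0.73, percentile 87.6), with Oas1a 254-fold higher (133 to 557).

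Markers of other lineages were mixed between iPSCs and Day 2. Blood and macrophage genes were higher in 13 and lower in 1 of 17 (median 6.54, or 4.86 with zeros at 3 reads; percentile 100). Primitive endoderm genes were higher in 6 and lower in 5 of 11 (median 5.62, or 3.99 with zeros at 3 reads; percentile 100), and the basement membrane gene Lama1 was at least 173-fold higher. Neural genes were higher in 8 and lower in 3 of 15 (median 1.74, or 1.10 with zeros at 3 reads; percentile 97.6), though Nes, the intermediate filament of neural progenitors, was 22.2-fold lower (18.8 to 26.3). Trophoblast genes were higher in 5 and lower in 4 of 15, with Tfap2c at least 1532-fold higher and Krt7 at least 89.9-fold lower. Muscle genes split 4 and 4 of 8 (median -0.06), endothelial genes were higher in 4 and lower in 1 of 9 (Tek at least 37.6-fold higher), and imprinted genes were higher in 10 and lower in 11 of 26 (median -0.14), with the growth factor Igf2 412-fold lower (114 to 3403). In total 2517 genes were higher in iPSCs and 2595 lower, of 13981 compared; 1406 of the higher genes had no read at Day 2 and 762 of the lower genes none in iPSCs. Without genes lacking a read in either library, the higher count was 1111. With no filter on low values it was 5142 and with the filter at 8 it was 1347, and in each of the other 6 comparisons the filter moved at least 1 count by over 1.5 times.

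**Figure D1:**
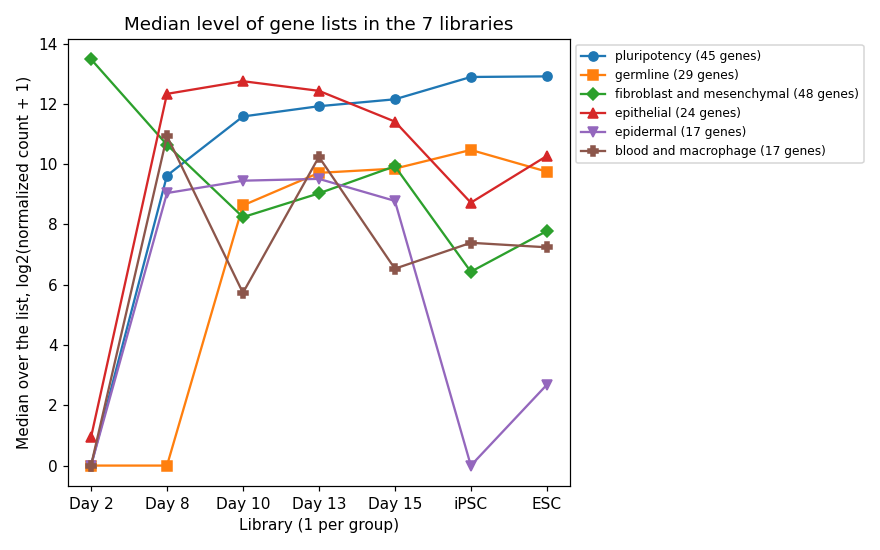
Median log2 normalized count (y axis) of gene lists in the 7 libraries (x axis), each line a list and each point 1 library. The pluripotency median was 0.00 at Day 2 and 9.62 at Day 8, the fibroblast median 13.48 at Day 2 and 8.24 at Day 10, and the blood and macrophage median 10.93 at Day 8, 5.73 at Day 10 and 10.24 at Day 13.

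Between Day 2 and Day 8, when SSEA1-positive cells were first sorted, most epithelial and most pluripotency genes stood higher. These differences hold both the passage of time and the sort. Epithelial genes were higher in 23 and lower in 0 of 24 (median 10.82, or 9.66 with zeros at 3 reads; percentile 100): the tight-junction gene Cldn4 was at least 6520-fold higher, Epcam at least 6032-fold and Cdh1 at least 2168-fold. Pou5f1 was at least 6575-fold higher and Sox2 at least 859-fold. Counts per gene do not separate vector transcripts from those of the cell's own genes. This limits Pou5f1, Sox2, Klf4 and Myc in the intermediates, and all but Myc are in the pluripotency list. The iPSCs were kept without doxycycline. Of 45 pluripotency genes 33 were higher and 4 lower (median 8.83, or 6.92 with zeros at 3 reads; percentile 100), with the threonine dehydrogenase Tdh at least 4108-fold, Sall4 at least 1507-fold and L1td1 at least 1072-fold higher. Nanog was 1830-fold higher (626 to 8875, on 3 reads at Day 2), Esrrb at least 279-fold, Zfp42 at least 862-fold and Dppa4 at least 300-fold, while Prdm14 had no read in either library. Klf4 was 26.2-fold higher (23.4 to 29.4). Fut9, the fucosyltransferase that makes the SSEA1 epitope, was at least 230-fold higher.

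Other genes furthest above Day 2 at Day 8 were the membrane protease St14 (at least 5830-fold), Ly6g6c (5414), the calcium pump Atp2a3 (5310), Dnah17 (5172) and Lcp1, the actin bundler of blood cells (4388), each also a lower bound. Fibroblast and mesenchymal genes were lower in 43 and higher in 4 of 48 (median -3.16, percentile 0): the PDGF receptor Pdgfra was at least 286-fold lower, smooth muscle actin Acta2 432-fold (407 to 459) and Thy1 102-fold (62.4 to 178). The genes furthest below were Inhba, at 44888-fold (8056 to 1773007, on 1 read at Day 8), and, as lower bounds, Lrrc32 (11886-fold), the cartilage collagen Col2a1 (10823), the contractile gene Cnn1 (9075), Ppbp (8187), the gap junction gene Gjb2 (6018), the actin-binding gene Dbn1 (5353) and the peptide hormone gene Adm (5095). Hox genes were lower in 19 and higher in 1 of 23 (median -6.57, or -4.79 with zeros at 3 reads; percentile 0), with Hoxa10 at least 381-fold lower.

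Markers of other cell types moved with the Day 8 library. Blood and macrophage genes were higher in 16 and lower in 0 of 17 (median 9.98, or 8.61 with zeros at 3 reads; percentile 100): the complement gene C1qb was at least 1779-fold higher, the Fc receptor subunit Fcer1g at least 1149-fold and the leukocyte antigen Ptprc (CD45) at least 864-fold. Epidermal genes were higher in 10 and lower in 0 of 17 (median 2.43, percentile 100), with the keratin Krt17 at least 2086-fold higher. Glycolysis genes were higher in 8 and lower in 1 of 19 (median 0.62, percentile 99.9): Aldoc was 156-fold (111 to 226) and Slc2a3 90.1-fold (78.2 to 104) higher. The mitochondrial genome's transcripts were higher in 8 of 10 (median 1.32, percentile 100). Germline genes were higher in 5 and lower in 2 of 29, and X-linked germline genes higher in 4 and lower in 1 of 26, both with a median of 0.00. In total 2192 genes were higher and 2950 lower of 13475 compared; 1042 of the higher and 1633 of the lower genes had no read in the library they were lower in. With reads required in both libraries the counts were 1150 and 1317, and with Day 10 in place of Day 8 the lower count was 1952.

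From Day 8 to Day 10 most germline and most pluripotency genes stood higher. Prdm14 went from 0 to 730 reads, at least 232-fold higher, and Otx2, a factor of formative pluripotency, was at least 1166-fold higher. Germline genes were higher in 22 and lower in 0 of 29 (median 6.92, or 5.14 with zeros at 3 reads; percentile 100), with the tubulin Tuba3a at least 749-fold and Hormad1 at least 494-fold higher. X-linked germline genes were higher in 24 and lower in 0 of 26 (median 4.93, or 3.47 with zeros at 3 reads; percentile 98.4), among them the homeobox genes Rhox6 (at least 318-fold) and Rhox9 (at least 268-fold). Formative genes were higher in 14 and lower in 1 of 17 (median 6.41, or 4.74 with zeros at 3 reads; percentile 100), with Fgf5 229-fold (98 to 708) and Fgf15 566-fold (101 to 22403, on 1 read at Day 8) higher. Pluripotency genes were higher in 32 and lower in 0 of 45 (median 1.89, percentile 100): Nodal was at least 869-fold, Tbx3 at least 531-fold and Esrrb 3.58-fold (3.33 to 3.85) higher.

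The genes furthest apart between Days 8 and 10 also included Upp1 (at least 3161-fold higher at Day 10), Morc1, a repressor of transposons in male germ cells (1350), and Ubr7 (1224). Blood and macrophage genes were lower at Day 10 in 16 and higher in 1 of 17 (median -5.11, percentile 0), with the myeloid factor Spi1 at least 740-fold lower, Mpeg1 at least 639-fold and C1qb 137-fold (102 to 187). The lowest genes were Wfdc18 (at least 3111-fold lower), the chemokine Ccl3 (1889), the lysosomal protease Ctss (1436) and the collagenase Mmp13 (1304). Fibroblast genes were lower in 32 and higher in 3 of 48 (median -2.25, percentile 0), trophoblast genes higher in 9 and lower in 0 of 15 (percentile 97.3; Tfap2c at least 696-fold, Plac1 at least 263-fold), and imprinted genes higher in 14 and lower in 3 of 26 (median 1.07, percentile 99.8; H19 21.2-fold, 18.7 to 24.1). Epithelial genes stayed within 2-fold in 21 of 24. In total 2742 genes were higher and 1245 lower of 13716 compared, and 1798 of the higher genes had no read at Day 8. With reads required in both libraries the higher count was 944, and with Day 2 in place of Day 8 the lower count was 1952.

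Between Days 10 and 13 blood and macrophage genes differed most. They were higher at Day 13 in 16 and lower in 0 of 17 (median 3.71, percentile 100), and the 4 largest differences overall were Ccl8, Ctss, Plek and Mpeg1, genes of myeloid cells: the monocyte chemokine Ccl8 was at least 867-fold higher, Ctss at least 695-fold, the pleckstrin gene Plek at least 500-fold and the perforin-like gene Mpeg1 at least 341-fold. Spi1 was at least 223-fold and C1qa 73.5-fold (52.4 to 106) higher. Formative and early germ-layer genes were higher in 12 and lower in 0 of 17 (median 1.49, percentile 100), with Mixl1 17.3-fold (13.1 to 23.3), Zic2 16.3-fold (9.1 to 32.3) and the Nodal antagonist Cer1 9.58-fold (8.23 to 11.2) higher. Fibroblast genes were higher in 22 and lower in 1 of 48 (median 0.77, percentile 100). Interferon response genes were higher in 11 and lower in 0 of 23 (median 0.90, percentile 98.9) and inflammation genes higher in 9 and lower in 2 of 18 (median 1.07, percentile 98.8), with the antiviral gene Mx1 at 0 and 110 reads and the chemokine Ccl2 7.09-fold (6.05 to 8.36) higher.

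Pluripotency genes differed little between Days 10 and 13, with 1 higher and 3 lower of 45 (median 0.14, percentile 96.4), though Klf4 was 2.69-fold lower (2.55 to 2.84). Germline genes were higher in 10 and lower in 3 of 29 (median 0.83, percentile 99.2). All 39 ribosomal protein genes were within 2-fold, with a median of 0.38 (percentile 100). The genes furthest below were the intestinal brush-border myosin Myo1a (at least 164-fold lower), the skin lipid enzyme gene Pnpla1 (122), Ces2b (93) and Myo18b (79). In total 997 genes were higher and 401 lower of 14089 compared. Taking Day 15 in place of Day 13 gave 1583 and 962.

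Between Days 13 and 15 the same blood and macrophage list was lower in 14 and higher in 0 of 17 (median -3.22, percentile 0): Ccl8 was at least 1159-fold lower, the coagulation factor gene F13a1 at least 1099-fold, the leukocyte receptor Cd84 at least 365-fold and the lysozyme genes Lyz1 151-fold (94.3 to 261) and Lyz2 32.5-fold lower. Plau, the urokinase gene, was at least 333-fold lower. X-linked germline genes were higher at Day 15 in 19 and lower in 0 of 26 (median 2.07, percentile 100), with Magea4 at least 62.6-fold and Magea8 at least 40.6-fold higher. Nanog was 2.05-fold (1.99 to 2.11), Zfp42 2.38-fold (2.31 to 2.45) and Esrrb 1.96-fold (1.86 to 2.07) higher. Pluripotency genes were higher in 9 and lower in 1 of 45 (median 0.37, percentile 100). Of 155 genes with at least 10 reads in iPSCs and none at Days 2, 8, 10 and 13 or in ESCs, all 155 had reads at Day 15, at a median of 34.2% of the iPSC level. With 34.2% of the iPSC values removed from Day 15 the pluripotency median was -0.65, and with the lowest share, 26.2%, it was -0.11. The X-linked germline list is open to the same share, with median levels of 6.11 at Day 13, 7.62 at Day 15 and 8.63 in iPSCs. Its rise, with Magea4 and Magea8, and the rises of Nanog, Zfp42 and Esrrb may therefore partly reflect that share.

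Fibroblast genes were higher at Day 15 than at Day 13 in 29 and lower in 4 of 48 (median 1.20, percentile 100), although the hyaluronan receptor Cd44 was 8.85-fold and the mesenchymal factor Tbx15 at least 214-fold lower. Epithelial genes were lower in 9 and higher in 0 of 24 (median -0.83, percentile 0), epidermal genes lower in 11 and higher in 2 of 17 (median -1.30, percentile 0.01), glycolysis genes lower in 4 of 19 (median -0.58, percentile 0; Aldoc 3.81-fold, 3.57 to 4.07) and neural genes lower in 8 and higher in 2 of 15 (median -1.15, percentile 0.04). Imprinted genes were higher in 11 and lower in 1 of 26 (median 0.87, percentile 100): the zinc finger gene Plagl1 was 4.89-fold (4.17 to 5.76) and Nnat 4.3-fold (3.93 to 4.72) higher, and the placental growth regulator Phlda2 5.1-fold (4.69 to 5.57) lower. The endoderm factor Sox17 was 6.24-fold higher (5.3 to 7.41), in a primitive endoderm list with 6 higher and 2 lower of 11 (median 1.18, percentile 99.7). Mitochondrial genome transcripts were higher in 9 of 10 (median 1.52, percentile 100). Scube1 (at least 495-fold), the protease Tmprss2 (211), Stk33 (195) and the Tie2 ligand Angpt1 (149) were furthest above Day 13. In total 930 genes were higher and 882 lower of 14615 compared, and with Day 10 in place of Day 13 the higher count was 1583.

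The comparison of iPSCs with Day 15 was one-sided: 35 genes were higher in iPSCs and 1849 lower, of 14216 compared. None of the 35 had 0 reads at Day 15, and 788 of the lower genes had 0 reads in iPSCs. Among the genes furthest below, the retinoic acid hydroxylase Cyp26a1 was at least 602-fold lower, Lox at least 457-fold, Igfbp5 at least 432-fold, the pentraxin Ptx3 at least 407-fold, the keratin Krt7 at least 397-fold, Col8a1 at least 357-fold, the morphogen Shh at least 344-fold and Svep1 at least 262-fold. Fibroblast genes were lower in 38 and higher in 0 of 48 (median -3.76, or -3.38 with zeros at 3 reads; percentile 0), with periostin (Postn) at least 259-fold lower. Epithelial genes were lower in 16 and higher in 0 of 24 (median -1.80, percentile 0): Krt19 was 226-fold (115 to 524), Krt8 70-fold (59.5 to 83) and Epcam 2.44-fold (2.32 to 2.57) lower. Epidermal genes were lower in 13 and higher in 0 of 17 (median -4.77, or -2.66 with zeros at 3 reads), with Krt14 at least 234-fold lower. Formative and germ-layer genes were lower in 10 and higher in 0 of 17 (median -1.12, percentile 1.79): Foxa2 was at least 80.3-fold and Cer1 93.1-fold (50.6 to 194) lower, and the mesoderm factor T (brachyury) stood at 2414 reads at Day 15 and 21 in iPSCs.

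The medians of the pluripotency and germline lists were higher in iPSCs than at Day 15, though most members stood within 2-fold. Over 9427 genes with at least 100 iPSC reads the lowest Day 15 to iPSC ratio was 26.2%. No such gene could therefore stand far above Day 15, and the small differences are not a measure of nearness to the iPSC state. Of 45 pluripotency genes 12 were higher and 1 lower (median 0.86, percentile 100), with Nr5a2 at 2.7-fold (2.31 to 3.14), Tfcp2l1 2.66-fold, Tbx3 2.59-fold, Klf2 2.58-fold, Nanog 2.38-fold (2.33 to 2.43) and Zfp42 2.42-fold (2.37 to 2.48). X-linked germline genes were higher in 14 and lower in 2 of 26 (median 1.08, percentile 100), and germline genes higher in 8 and lower in 2 of 29 (median 0.77, percentile 100). Immediate early genes were lower in 12 of 16 (median -1.63, percentile 0; Fosl2 at least 64-fold), inflammation genes lower in 10 and higher in 1 of 18 (median -1.70, or -1.07 with zeros at 3 reads; percentile 0.52), imprinted genes lower in 13 and higher in 0 of 26 (median -0.90, percentile 0.01; Cdkn1c 60.6-fold, 29.4 to 151) and glycolysis genes lower in 5 of 19 (median -0.59, percentile 0; Aldoc 6.99-fold, 5.21 to 9.6). Blood and macrophage genes were higher in 11 and lower in 2 of 17 (median 1.35, percentile 100). The largest single differences above Day 15 were Spdye4b (8.36-fold, 4.28 to 17.1), the sodium channel Scn2a (6.16), Pik3r6 (5.68), the interferon factor Irf7 (5.62), Platr31 (5.38), Cfap46 (5.17), Tmem82 (5.09) and Slc27a5 (4.78). The count of 35 higher genes was 89 with median centring and 0 with a pseudocount of 16. With Day 13 in place of Day 15 it was 671, and with 26.2% or 34.2% of the iPSC values removed from Day 15 it was 859 or 1148.

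**Figure D2:**
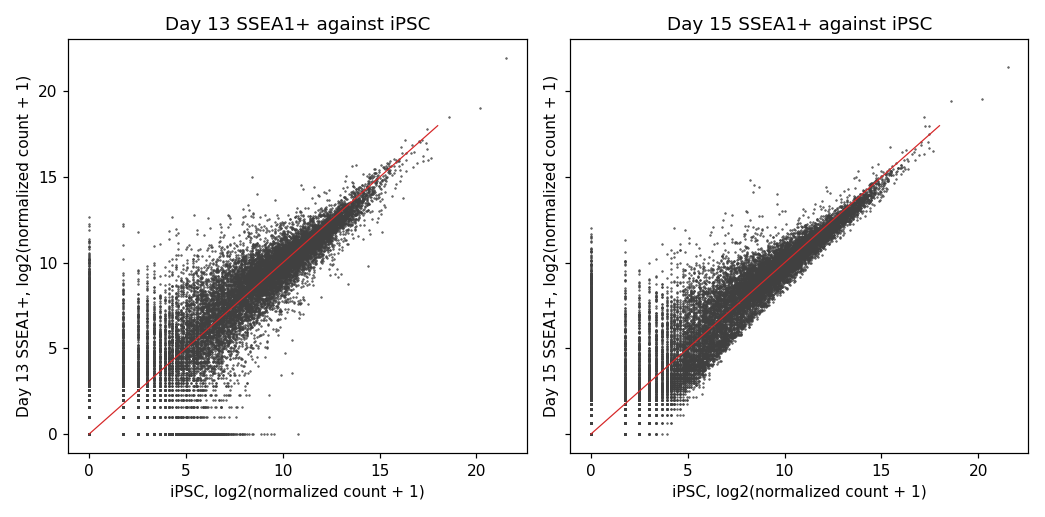
Log2 normalized count in the Day 13 library (left) and the Day 15 library (right) on the y axis against that in the iPSC library on the x axis, each point 1 gene and the line marking equality. Over 9427 genes with at least 100 iPSC reads the lowest ratio to iPSCs was 0% at Day 13, where 15 genes had no read, and 26.2% at Day 15, where 0 genes had none.

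The ESC library served as the reference for the iPSCs. The ESCs did not come from the reprogrammed fibroblasts, so origin and cell state cannot be told apart in this comparison. Pluripotency genes were close, with 2 higher and 2 lower of 45 (median -0.16, percentile 6.31): Klf2 was 3.96-fold and Tfcp2l1 2.68-fold lower in ESCs, and the Nodal antagonist Lefty1 3.44-fold and Dnmt3b 2.13-fold higher. Nanog was 1.63-fold lower (1.6 to 1.67) and Pou5f1 1.12-fold lower (1.09 to 1.14). Two-cell-like genes, transcripts of the zygotic genome activation stage, were higher in ESCs in 7 and lower in 0 of 9 (median 3.92, or 3.37 with zeros at 3 reads; percentile 99.3). Tdpoz4 was at least 12.1-fold, Usp17la at least 11.7-fold and Tcstv3 at least 11.2-fold higher. Fibroblast genes were higher in 23 and lower in 5 of 48 (median 0.94, percentile 100) and epithelial genes higher in 13 and lower in 0 of 24 (median 1.14, percentile 100), with Krt19 11.9-fold, the claudin Cldn3 10.8-fold and Epcam 2.77-fold (2.63 to 2.93) higher. Germline genes were lower in 10 and higher in 1 of 29 (median -0.64, percentile 0.72), among them Asz1 at least 44.1-fold and the piRNA helicase Mov10l1 11.8-fold.

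All 10 measured transcripts of the mitochondrial genome were higher in ESCs than in iPSCs, with a median ratio of 9.66, and the cytochrome oxidase subunit mt-Co1 was 12.8-fold higher. Nuclear genes of oxidative phosphorylation were all within 2-fold (40 of 40, median 0.02, percentile 66.6), as were 39 of 39 ribosomal protein genes (median 0.20, percentile 100). Primitive endoderm genes were lower in 6 and higher in 2 of 11 (median -1.04, percentile 0.35), with Sox17 and Amn at least 34.7-fold lower. Endothelial genes were higher in 5 and lower in 0 of 9 (median 1.81, or 0.42 with zeros at 3 reads; percentile 98.3), and X inactivation escapees higher in 3 and lower in 0 of 10 (median 0.47, percentile 99). Imprinted genes split 4 and 4 of 26, with the antisense RNA Airn 28.1-fold (4.86 to 1129) and the growth inhibitor Cdkn1c 15.4-fold (7.36 to 38.8) higher and the deiodinase Dio3 at least 116-fold lower.

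The genes furthest above the iPSCs in ESCs were Wnt8a (at least 92.4-fold), Foxi3 (80.2), Tnc (64.3), Pou6f1 (62.7), Enpp2, which makes lysophosphatidic acid (62.3), the cadherin Cdh15 (62.3), the interferon-induced GTPase Gbp2 (61.6) and Sdk1 (61.5). Those furthest below were Ttc39c (at least 185-fold), Angptl7 (153), Zscan20 (146), Hhat, which acylates hedgehog proteins (142), Cables1 (125), the potassium channel genes Kcng1 (122) and Kcnab3 (119), and Dio3. On chromosome X, Magee2 (at least 28-fold), Nyx (21.5), Xkrx and Bmp15 (17.5 each) and Gpr50 (15.1) were furthest above, and Magea8 (67.2), Taf9b (62.2), Gpr143 (52.8) and Ppef1 (49.9) were among those furthest below. In total 993 genes were higher and 863 lower of 13592 compared.

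The X-linked genes were compared as a class to follow expression from the X relative to the autosomes over the course. Over 420 X-linked and 10807 autosomal genes, the X-linked median relative to the autosomal median stood at -0.02 on the log2 scale at Day 8 minus Day 2 (interval -0.18 to 0.07, percentile 46.44). It was 0.25 at Day 10 (0.04 to 0.40, 1.19-fold), 0.41 at Day 13 (0.24 to 0.51, 1.33-fold) and 0.58 at Day 15 (0.39 to 0.75, 1.49-fold). In iPSCs it reached 0.80 (0.54 to 1.05, 1.74-fold), with 290 of 420 X-linked genes (69%) above the autosomal median, and in ESCs 0.76 (0.58 to 0.98, 1.69-fold). The iPSCs and ESCs were sorted for GFP as well as SSEA1, the later intermediates for SSEA1. As the protocols name an X-GFP reporter, selection for an active reporter X cannot be told apart from the course in the iPSC and ESC values. From Day 10 on, 0 of 10000 random autosomal lists were as high. Between successive libraries the X-linked difference was 0.40 from Day 8 to Day 10, 0.26 to Day 13, 0.14 to Day 15 and 0.33 to iPSCs, and between iPSCs and ESCs -0.06 (-0.13 to 0.00). Among genes that differed by less than 2 between Day 2, iPSC and ESC, the values were -0.05 at Day 10, 0.13 at Day 13, 0.12 at Day 15, 0.36 in iPSCs and 0.38 in ESCs, so the sign at Day 10 reversed. Among genes with reads in all 7 libraries they were 0.08 at Day 10, 0.26 at Day 13, 0.36 at Day 15, 0.50 in iPSCs and 0.52 in ESCs, and with Day 8 in place of Day 2 the Day 13 value was 0.64. With 34.2% of the iPSC values removed from Day 15 the Day 15 value was 0.42, and with 26.2% removed 0.46, close to the 0.41 of Day 13, so the rise from Day 13 to Day 15 depends on this share. A fallback list of 185 X-linked genes, fixed in advance, had a median of 0.10 at Day 10 minus Day 2 (40 higher and 39 lower, percentile 79.9) and 0.33 at Day 13 (49 and 28, percentile 100). The value at Day 10 thus depends on the genes taken.

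**Figure D3:**
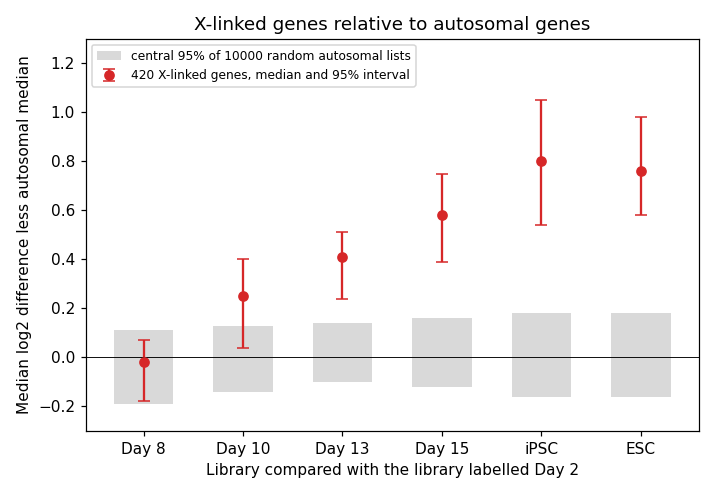
Median log2 difference from the Day 2 library of 420 X-linked genes less that of 10807 autosomal genes (y axis) in 6 libraries (x axis), with 95% intervals of the median and the central 95% of 10000 random autosomal lists as bars. The values were -0.02 at Day 8, inside the random range, and 0.25 at Day 10 to 0.80 in iPSCs, above it.

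Among single X-linked genes, Bex1, Trap1a (at least 4968-fold), Bex4 (at least 3844-fold), the nuclear receptor Nr0b1 (Dax1; at least 2737-fold) and Mcf2 (at least 2729-fold) stood furthest above Day 2 in iPSCs. The matrix proteoglycan Bgn was 1185-fold lower (848 to 1711), and Rtl3 (at least 444-fold), Srpx2 (119), Srpx (103) and Sytl5 (67.5) were the others furthest below. Genes known to escape X inactivation were higher in iPSCs than at Day 2 in 5 and lower in 2 of 10 (median 0.87, percentile 94.5). The histone demethylases Kdm6a and Kdm5c were 5.3-fold (4.81 to 5.84) and 3.02-fold (2.86 to 3.19) higher, the helicase Ddx3x 2.14-fold (2.06 to 2.21) and Eif2s3x 1.26-fold (1.17 to 1.34), and Mid1 was 8.15-fold lower (5.78 to 11.9). Kdm6a differed most from Day 8 to Day 10, at 6.94-fold higher (6.31 to 7.65).

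Xist, the noncoding RNA that coats the inactive X (GRCm38 chromosome X, 103460366 to 103483254), stood at 12.23 at Day 2, 12.78 at Day 8, 12.10 at Day 10, 12.13 at Day 13 and 13.01 at Day 15 on the log2 scale, and at 9.87 in iPSCs and 9.96 in ESCs. It was 5.12-fold lower in iPSCs than at Day 2 (4.62 to 5.68) and 8.81-fold lower than at Day 15 (7.98 to 9.75). Its antisense gene Tsix (103431517 to 103484957) had no read at Day 2 and 2 at Day 8, and was 50-fold higher at Day 10 than at Day 8 (13.5 to 418). It reached 7.15 in iPSCs, at least 51.3-fold above Day 2. Tsix overlaps Xist in full, and the library kit does not separate the strands. The neighbouring noncoding genes Jpx and Ftx, activators of Xist, were 4.16-fold (3.21 to 5.46) and 4.73-fold (4.06 to 5.53) higher at Day 8 than at Day 2. In iPSCs Jpx had no read and Ftx was 4.26-fold lower than at Day 15 (3.14 to 5.92). Rlim, the X-linked ubiquitin ligase that activates Xist, was 2.23-fold higher at Day 10 than at Day 8 (2.18 to 2.27) and 1.05-fold lower in iPSCs than at Day 15 (1.02 to 1.08). Centring on the medians turned the iPSC to Day 15 difference of Rlim, to 0.06. Of 26 X inactivation regulators 11 were higher and 4 lower in iPSCs than at Day 2 (median 0.53, percentile 92.9), with Hnrnpu, which anchors Xist RNA, 14.2-fold higher (13.6 to 14.8) and Cdyl 9.22-fold (8.15 to 10.4).

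**Figure D4:**
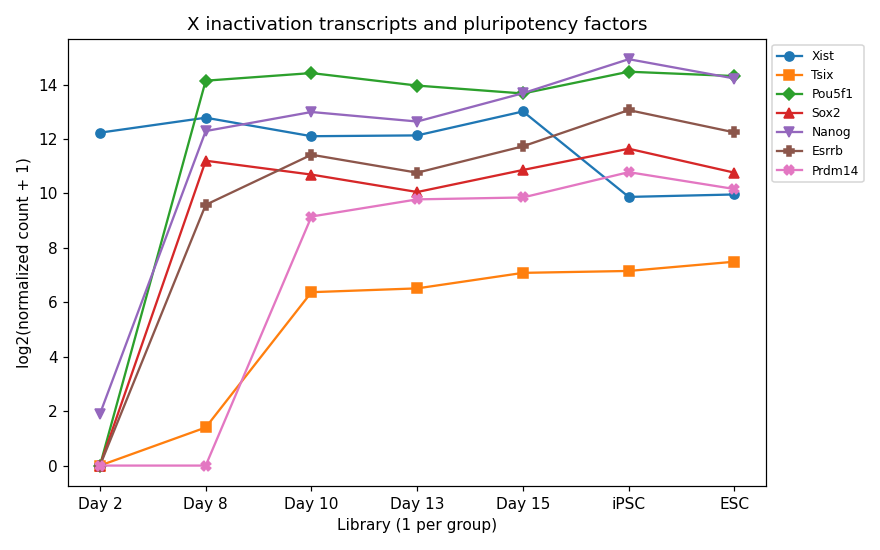
Log2 normalized count (y axis) of Xist, Tsix, Pou5f1, Sox2, Nanog, Esrrb and Prdm14 in the 7 libraries (x axis), each point 1 library. The counts of Pou5f1 and Sox2 do not separate vector from endogenous transcripts. Xist stood between 12.10 and 13.01 from Day 2 to Day 15 and at 9.87 in iPSCs, and Prdm14 stood at 0.00 at Days 2 and 8 and at 9.15 at Day 10.

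The order of changes over the course was read from the share of genes past the midpoint of their iPSC minus Day 2 change. Of the 2517 genes higher in iPSCs, 36.4% had passed it at Day 8 (34.5 to 38.3), 77.5% at Day 10 (75.8 to 79.1), 84.7% at Day 13 (83.2 to 86.1) and 98.5% at Day 15 (97.9 to 98.9). All 17 epithelial genes of this set had passed it at Day 8, as had 66.7% of 45 pluripotency genes (52.1 to 78.6), but 15.4% of 26 germline genes (6.15 to 33.5) and 8.33% of 24 X-linked germline genes (2.32 to 25.8). The pluripotency genes include Pou5f1, Sox2 and Klf4, for which vector transcripts in the intermediates could not be told apart. By Day 10 the germline genes stood at 92.3% and the X-linked germline genes at 79.2%. X-linked genes were behind autosomal genes at Day 8, with 23.1% of 216 (18 to 29.2) against 37.9% of 2248 (36 to 40), and near them at Day 10, with 73.6% (67.4 to 79) against 78% (76.2 to 79.6). Genes lower in iPSCs did not progress in this way: 57.8% of 2595 were past the midpoint at Day 8, 58.8% at Day 10, 54.8% at Day 13 and 57.1% at Day 15. Of 46 fibroblast genes the share was 34.8% at Day 8, 76.1% at Day 10, 69.6% at Day 13 and 54.3% at Day 15. With iPSC values removed from Day 15, the rising share at Day 15 was 85.1% (26.2% removed) or 73.8% (34.2% removed), against 84.7% at Day 13. At 75% of the way in place of the midpoint, the falling share was 33.8% at Day 13 and 34.3% at Day 15. Of 9427 genes with at least 100 iPSC reads, 818 had no read at Day 8, against 39 at Day 10. Transcripts lost from the Day 8 library would lower its rising shares and raise its falling shares. How much of the step from Day 8 to Day 10 rests on such losses is not known. Day 2, where each change starts, carries no label of an SSEA1 sort, so the order holds both time and sorting.

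Over the course, 266 genes were higher in all 4 sorted intermediates than in each of Day 2, iPSCs and ESCs, and 14 were lower. Of those furthest above, the skin protease Asprv1 (margin 9.52 on the log2 scale), the uroplakin Upk1b (9.07), the cornified envelope gene Sprr1a (9.04), S100a14 (8.86), sciellin, Scel (8.82), the adhesion molecule Ceacam1 (8.81), the kallikrein Klk14 (8.62), Cyp26a1 (8.48), the mucin Muc4 (8.36) and Misp (8.23) had no read in Day 2, iPSCs or ESCs. The 266 genes included 9 of the epithelial list, with the keratins Krt8, Krt18 and Krt19 and the claudins Cldn3 and Cldn4, 5 of the epidermal list and the trophoblast factors Elf5 and Hand1. Of the 266 genes 1 was X-linked, and of the 14 lower genes 3 were. With provisional symbols left out, the genes furthest below were Rgs5 (2.16), Ly6g5b (1.83), Ahrr (1.66), Zfp964 (1.61) and the X-linked Tmem35a (1.38). Leaving out the Day 15 library gave 566 genes above and 102 below, and leaving out Day 2 gave 697 and 202. A margin of 2 gave 167 and 1, a pseudocount of 16 left 5 below, and removing 26.2% or 34.2% of the iPSC values from Day 15 gave 31 or 43 below.

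By chromosome, the autosomal medians furthest from the others were those of chromosome 1 in comparisons with the iPSC library. In comparisons without it, chromosome 18 stood at -0.25 against all autosomes in Day 8 minus Day 2, and chromosome 1 at 0.24 in Day 15 minus Day 13. These medians are over genes with a mean at or above 6, where chromosome 1 stood at -0.57 in ESC minus iPSC over 638 genes. The values that follow are over genes with a mean at or above 8, 497 of chromosome 1 and 7957 of the other autosomes. Relative to those autosomes, the chromosome 1 median was 0.61 higher in iPSCs than in ESCs (0.55 to 0.65) and 0.53 higher than at Day 13 (0.43 to 0.62). Prdm14 and Hnrnpu lie on chromosome 1. The ESC library stood at -0.10 against Day 13 (-0.18 to -0.00).

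**Figure D5:**
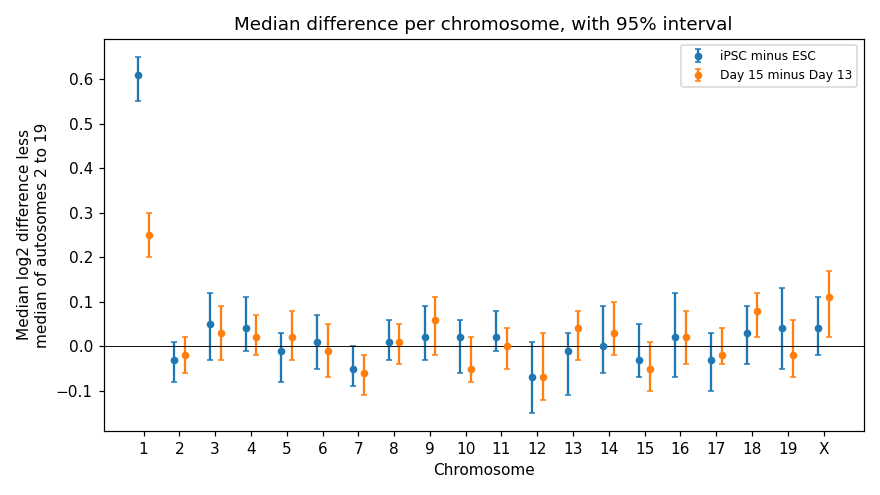
Median log2 difference of the genes of each chromosome less the median of autosomes 2 to 19 (y axis) by chromosome (x axis), for iPSC minus ESC and Day 15 minus Day 13, with 95% intervals of the median. Genes had a mean at or above 8. Chromosome 1 stood at 0.61 in iPSC minus ESC and at 0.25 in Day 15 minus Day 13, and autosomes 2 to 19 lay between -0.07 and 0.05 in the former.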

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

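Tests with swapped or left-out libraries, with reads required in each library, without chromosome 1, or with an iPSC share removed from Day 15 were chosen after the results had been seen. Median centring was planned for the gene counts, and the pseudocount of 16 for the gene counts, X-linked genes and transient genes. Both were added for lists and named genes after the results had been seen. Of 173 alternative values of the main results 99 stayed within their limit of change, 73 moved further and 1 reversed. Of 1034 for gene lists and named genes 835 stayed, 196 moved and 3 reversed. No paired analysis was possible because each group had 1 library. Depth limits genes near the floor of 3 reads, most in the iPSC library (15370903 reads).

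With no filter on low values more genes were counted, by construction: 5142 higher in iPSC minus Day 2, 4763 lower in Day 8 minus Day 2 and 6463 higher in Day 10 minus Day 8. Higher and lower counts were 3408 and 1810 in Day 13 minus Day 10, 2859 and 2696 in Day 15 minus Day 13, 335 and 3838 in iPSC minus Day 15, and 2795 and 2722 in ESC minus iPSC. With the filter at 8 fewer genes were compared: 1347 were higher in iPSC minus Day 2, 1912 lower in Day 8 minus Day 2 and 1225 higher in Day 10 minus Day 8. Higher and lower counts were then 292 and 99 in Day 13 minus Day 10, 291 and 339 in Day 15 minus Day 13, 0 and 786 in iPSC minus Day 15, and 236 and 220 in ESC minus iPSC. With reads required in both libraries, which removes genes at 0, 1111 were higher in iPSC minus Day 2, 1150 higher and 1317 lower in Day 8 minus Day 2, and 944 higher in Day 10 minus Day 8.

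Median centring gave 89 higher genes in iPSC minus Day 15 and turned Rlim in that comparison, to 0.06. It moved the median of all genes from 0.02 to 0.25 in iPSC minus Day 2 and from -0.02 to 0.12 in iPSC minus Day 15. A pseudocount of 16, which shrinks low values, left 0 higher genes in iPSC minus Day 15 and 5 transient genes below.

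Swapping libraries changed the counts, and the cause was not tested. These swaps are other comparisons rather than other processing, and some enter the 173 values above more than once. Day 8 minus Day 2 with Day 10 in place of Day 8, and Day 10 minus Day 8 with Day 2 in place of Day 8, are both Day 10 minus Day 2, with 1952 lower genes. Day 13 minus Day 10 with Day 15 in place of Day 13, and Day 15 minus Day 13 with Day 10 in place of Day 13, are both Day 15 minus Day 10, with 1583 higher and 962 lower. For iPSC minus Day 15, Day 13 in place of Day 15 gave 671 higher genes.

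Removing the lowest iPSC share (26.2%) from Day 15 gave 859 higher genes in iPSC minus Day 15, 85.1% of rising and 50% of falling genes past the midpoint, 31 transient genes below, an X-linked value of 0.46 at Day 15 (0.58 as reported) and a pluripotency median of -0.11 in Day 15 minus Day 13, where it had been 0.37. Removing the median share (34.2%), added after that outcome, gave 1148, 73.8%, 47.2%, 43, 0.42 and -0.65 for the same results.

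For X-linked genes the cause of the changes was not tested. Among genes that differed by less than 2 between the ends of the course, the values were -0.05 at Day 10 (reversed from 0.25), 0.13 at Day 13, 0.12 at Day 15, 0.36 in iPSCs and 0.38 in ESCs. Among genes with reads in all 7 libraries they were 0.08 at Day 10, 0.26 at Day 13 (0.41 as reported), 0.36 at Day 15, 0.50 in iPSCs and 0.52 in ESCs. Day 13 minus Day 8, in place of Day 2, gave 0.64.

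At 25% of the way, rising genes past the mark were 43% at Day 8, 85.9% at Day 10, 91.9% at Day 13 and 99.9% at Day 15, and at 75% of the way 28.7%, 55.2%, 65.8% and 82.4%. Falling genes were 71.4%, 78.5%, 77.2% and 78.3% at 25%, and 48.4%, 41.5%, 33.8% and 34.3% at 75%. Transient genes above numbered 167 with a margin of 2, 566 without Day 15 and 697 without Day 2. Transient genes below numbered 1, 102 and 202 under these. A stricter mark, a larger margin or fewer libraries change these numbers by construction.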

Other observations

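The tests of the 3 patterns below were all chosen after the results they concern had been seen. Abundant single genes of the blood and macrophage list followed it. Lyz2, the macrophage lysozyme, stood at 14.15 on the log2 scale at Day 8, 9.73 at Day 10, 14.56 at Day 13 and 9.54 at Day 15, against 7.63 at Day 2, 10.93 in iPSCs and 10.90 in ESCs. C1qb stood at 12.25 at Day 8, 5.20 at Day 10, 10.79 at Day 13 and 7.51 at Day 15, with no read at Day 2. The chemokine Ccl8 had 2067 reads at Day 13 and none in any other library. Median levels of the Hox list were 7.66 at Day 2, 0.00 at Days 8, 10 and 13, 4.33 at Day 15 and 0.00 in iPSCs and ESCs. The number of its 23 measured genes with a read was 23 at Day 2, 7 at Day 8, 10 at Day 10, 8 at Day 13, 15 at Day 15, 5 in iPSCs and 4 in ESCs.

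Endothelial, muscle, neural and two-cell-like genes also differed between libraries. Endothelial genes with a read numbered 2 of 9 at Day 2, 9 at Day 13 and 4 in iPSCs, and the Day 15 to Day 13 median was -2.29 (percentile 0.285), or -0.84 with zeros at 3 reads, with the vascular receptor Robo4 19.7-fold lower (15 to 26.4) and the VEGF receptor Kdr 8.02-fold higher (5.92 to 11.1). Muscle genes were lower in 5 and higher in 2 of 8 at Day 8 against Day 2 (median -5.63, or -3.84 with zeros at 3 reads), with skeletal actin Acta1 127-fold lower (89.8 to 186). The astrocyte filament gene Gfap had 646 reads at Day 13 and 11 at Day 15, 98.8-fold lower (54.9 to 199). Two-cell-like genes with a read numbered 0 of 9 at Day 2, 1 at Day 8, 1 at Day 10, 6 at Day 13, 7 at Day 15, 6 in iPSCs and 9 in ESCs.

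The Day 15 library stood apart in its relation to the iPSC library. Over 9427 genes with at least 100 iPSC reads the lowest Day 15 to iPSC ratio was 26.2%, while each of the other 41 ordered pairs of libraries had at least 15 genes at 0, and of 155 genes with at least 10 iPSC reads and none at Days 2, 8, 10 and 13 or in ESCs, all 155 had Day 15 reads. Depth of the Day 15 library does not account for this, since of 338 genes with at least 10 ESC reads and none at Days 2, 8, 10 and 13 or in iPSCs 23.7% had a Day 15 read. RNA, cDNA or reads of the iPSC sample in the Day 15 library are 1 candidate explanation. A share of the Day 15 cells already like the iPSCs is another. The first predicts a chromosome 1 shift of Day 15 minus Day 13 from the 34.2% share. The second predicts the same shift only if those cells also carried the chromosome 1 excess of the iPSC library, which was not tested. A shift of 0.20 was expected and 0.25 observed, a difference of 0.05 (resampling interval -0.00 to 0.10, which only just holds 0). These tests were revised after their outcome: in the first form the expected shift had no spread and lay just outside the observed interval (0.20 to 0.30), against carryover, while the other explanation needed only a shift above 0. The chromosome 1 shift thus does not separate carryover from iPSC-like cells that carry the same excess. Cells like the iPSCs without that excess would not predict it. In 0 of the 9427 genes were Day 15 reads fewer than iPSC reads, against 745 to 2189 genes in the other libraries. The Day 15 library was the deepest, and without replicates it is not known how far separately sampled iPSC-like cells would scatter. These values do not decide between the 2 explanations, and both stay open.

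Blood and macrophage genes stood higher at Days 8 and 13 than at Days 10 and 15. Depth of the Day 10 and Day 15 libraries does not account for this, since both had more reads than the Day 8 and Day 13 libraries: the fewest reads of the former pair were 1.03 times the most of the latter (42899719 at Day 10 and 41520563 at Day 8). An earlier form of this test measured the pattern itself and was dropped. A separate list of 32 such genes, of which 29 were measured and 0 belonged to the first list, was 2.93 higher at Day 8 than at Day 10 (22 genes at least 2-fold), 2.21 higher at Day 13 than at Day 10 (22 genes; random lists -0.29 to 0.98) and 3.36 higher at Day 13 than at Day 15 (27 genes). A candidate explanation is blood or macrophage cells in the sorted Day 8 and Day 13 samples, though the sort for SSEA1 would remove cells that lack it. Expression of these genes by the reprogramming cells themselves, a biological explanation, was not tested and stays open. The separate list cannot tell these explanations apart, since either would raise its genes.

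Genes of chromosome 1 were 0.61 higher in iPSCs than in ESCs relative to the other autosomes (0.55 to 0.65, 497 against 7957 genes with a mean at or above 8). A few genes or a single region of chromosome 1 do not account for this, since the 10 windows of 20 Mb had medians of 0.37 to 0.71, the thinnest with 15 genes. The scaling between libraries, 1 factor for every gene of a library, would move all autosomes alike. In values not centred on the other autosomes, chromosome 1 stood at 0.58 (0.52 to 0.62) and the highest other autosome, chromosome 3, at 0.02 (-0.06 to 0.09), a gap of 0.56. An earlier form of this test used centred values. Since such a factor cannot open a gap between chromosomes, neither form could turn out otherwise, and both restate the shift. The median ratio of 1.52 (1.46 to 1.57) is consistent with an extra copy of chromosome 1 in the iPSCs, a hypothesis from 1 library that was not tested on DNA. Day 13 against ESCs showed no such excess, with -0.10 for ESC minus Day 13, and no biological explanation from the design was tested.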
